A study of Mus musculus with 35 samples.

How the data were processed

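Gene expression was measured by RNA sequencing of total RNA from mouse gastrocnemius muscle, with libraries made with the TruSeq RNA Library Prep Kit v2, per the labels' protocols. The deposited table holds TPM (transcript abundances as parts of a fixed total) for 54416 gene IDs in 35 columns. Adapter trimming software cutadapt 1.16, the quantifier Salmon 1.1.0, edgeR (no version given) and the genome build GRCm38 are named per the submitters' processing notes, which do not say what each was used for. The transcript annotation, the gene lengths and the way transcripts were summed to genes are not stated. No depth per library can be computed from TPM, so the precision that depth gives is unknown and spread is measured between animals only. Column names state no age and no sample, so their groups are inferred: SO was taken as 24 months, since 6 MKO columns carry it and 5 do not, as the labels have 6 and 5 mKO samples, W or WT as WT, and MCK as mTG, the remaining genotype. No column was left out. The names carry no number shared between groups, so no pairing of animals was used. Libraries are named by group and column name. 54094 gene IDs matched the GRCm38 annotation, which gave symbols, gene types, transcript lengths and GC content, and 322 did not.

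Genes with at least 1 TPM in at least 5 libraries were tested, 12399 in all. log2(TPM + 1) values were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 35 libraries, a mean-variance trend in the empirical Bayes step, and Benjamini-Hochberg adjustment over genes within each comparison; genes with an adjusted p under 0.05 are called. The 7 comparisons of 2 groups were 24 against 3 months in WT, mKO and mTG, and mKO and mTG against WT at 3 and at 24 months, and the 2 interactions were the age effect in mKO or mTG minus that in WT. These comparisons, tests, the 40 gene lists, the rule for naming genes and most alternatives were set before the data were examined. Gene lists were tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over the 40 lists, and again with the correlation estimated from the data. Counts of list members "over the list alone" use Benjamini-Hochberg within the list.

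A single value per library was compared between groups by exact 2-sided permutation of the difference of means, whose smallest possible p is 0.00216, adjusted over the 7 comparisons. This was done for log2(TPM + 1) of Ppargc1a, the share of TPM in the 13 protein genes of mitochondrial DNA, the log2 share in nuclear rRNA genes, and, in 1 family of 42, the mean log2(TPM + 1) over the members of the 6 mitochondrial lists given as scores. The rRNA share was added after the values were seen. Interactions of scores were tested by permuting genotype within age (100000 resamples, smallest possible p 1e-05, family of 12). A genotype effect widens this null, so a high p does not exclude an interaction.

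Because the total of each column is fixed, an alternative chosen beforehand divided each column by the median over genes of its ratio to the geometric mean (median-of-ratios scaling, own code). The values so obtained are called scaled TPM. Its effect on the median gene exceeded 0.1 (log2) in several comparisons, so the report gives changes on scaled TPM and counts on both. Other alternatives chosen beforehand were a pseudocount of 0.1, no filter, a filter at a mean of 5 TPM, quantile normalization, removal of mitochondrial genes (not their copies), only the groups compared, array weights, a fold minimum of 1.5 and leaving out each library in turn. Alternatives added after results were seen were nuclear protein-coding genes only, the log2 rRNA share as a covariate with and without scaling, leaving out both libraries that lay apart on the third principal component with and without scaling, removal of the trend on transcript length after scaling, the mitochondrial share with pseudogene copies, and the list of translation factors without Lars2. Mitochondrial pseudogene copies were found with blastn 2.17.0 (identity of at least 95% over at least 80% of the gene).

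Named genes are Ppargc1a; the 6 largest rises and 6 largest falls of each comparison of 2 groups, on unscaled TPM, among called genes with a mean of at least 5 TPM in a group and no overlap of the groups, without Gm and Rik models, pseudogenes and mitochondrial genes; up to 4 members with the smallest adjusted p of each list described; and 5 genes per direction of each interaction. A gene named in 1 comparison may be followed in others. Which lists are described, which of those members are printed and which genes are followed were chosen after their values were seen. Some genes that met these rules are not reported here. So was a further set of protein-coding nuclear genes with the largest changes on scaled TPM, which the text marks.

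The fit was tested on simulated data made from the WT libraries, with 50 genes changed at each fold. On unscaled TPM 42% of 1.5-fold and 92% of 2-fold changes were recovered with 2 calls among 12198 unchanged genes, and on scaled TPM 78% and 96% with 9. When 1 gene was raised to take 15% of the total, unscaled TPM gave 3184 such calls and scaled TPM 11. For each count of genes, 100 splits of the libraries, the real one included, were fitted with only those libraries. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.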

Results

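The series compared gastrocnemius muscle of male mice by RNA sequencing at 3 and 24 months of age in 3 genotypes: wild type (WT), a muscle-specific knockout of PGC-1α (mKO) and a transgenic line with PGC-1α raised in muscle (mTG). PGC-1α, encoded by Ppargc1a, is a transcriptional coactivator that drives mitochondrial biogenesis, and the series title places the data in a study of mitochondrial translation, age and exercise. There were 35 libraries in 6 groups, with n = 6 per group except n = 5 for mKO at 3 months, and no library of exercised animals was among them. The values were TPM, transcript abundances given as parts of a fixed total, and each column added up to between 999999.5 and 1000000.3. TPM keep no read totals, so the depth of each library is unknown and no counting interval is given. Within groups, correlations of log2(TPM + 1) between libraries lay between 0.947 and 0.989.

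Ppargc1a (ENSMUSG00000029167, chromosome 5, 51454250 to 51567726, minus strand, GRCm38) was examined first, since its level checks the genotype labels. Its mean ± SD was 10.1 ± 4.99 TPM (range 5.69 to 18.8) in WT at 3 months (n = 6), 9.70 ± 4.44 TPM (range 5.20 to 15.7) in the libraries labelled mKO (n = 5) and 76.3 ± 6.87 TPM (range 66.5 to 83.6) in mTG (n = 6). At 24 months it was 4.27 ± 0.547 TPM (range 3.65 to 4.84) in WT, 10.8 ± 2.62 TPM (range 7.26 to 13.9) in the libraries labelled mKO and 62.8 ± 9.55 TPM (range 43.7 to 68.9) in mTG (n = 6 each). All 12 mTG libraries lay above all WT libraries of their age, with differences of 2.91 and 3.59 in mean log2(TPM + 1) at 3 and 24 months (2-sided exact permutation tests, adjusted p = 0.00379 over a family of 7 for both). For the libraries labelled mKO the difference from WT was -0.05 at 3 months (exact permutation test, adjusted p = 0.911) and 1.14 at 24 months, where all 6 lay above all 6 WT libraries (exact permutation test, adjusted p = 0.00379). A gene-level TPM sums all exons, and the labels do not state which part of the gene is deleted, so this value checks nothing about a partial deletion and every direction drawn from the libraries labelled mKO rests on the label. With age, Ppargc1a fell in WT by 0.97 with all 6 old libraries below all young ones (exact permutation test, adjusted p = 0.00379). In mTG the age difference was -0.29 (exact permutation test, adjusted p = 0.0121), which limma did not call (adjusted p = 0.447). For the libraries labelled mKO it was 0.22 (exact permutation test, adjusted p = 0.535). Each of these directions held after the scaling described below, with values of -0.70 for age in WT and 0.80 for mKO at 24 months (exact permutation tests, adjusted p = 0.00379 for both).

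**Figure D1:**
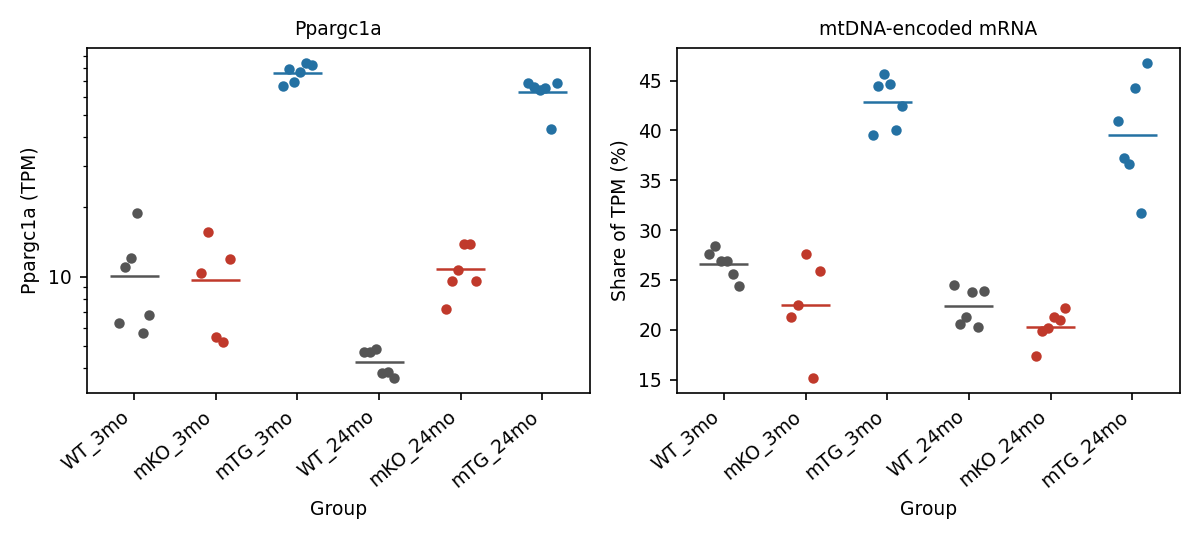
Ppargc1a in TPM on a log axis (left) and the share of total TPM in protein genes of the mitochondrial genome in percent (right), with 1 point per library in 6 groups and a bar at each group mean. Ppargc1a averaged 76.3 TPM in young mTG and 10.1 in young WT, and the libraries labelled mKO overlapped WT at 3 months and lay above it at 24 months.

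The makeup of the libraries differed strongly by age and genotype. RNA of nuclear ribosomal genes took 0.259% ± 0.124 (SD, n = 6) of TPM in WT at 3 months and 10.2% ± 2.65 at 24 months. In the libraries labelled mKO it went from 0.231% ± 0.0451 (n = 5) to 5.25% ± 3.20 (n = 6), and in mTG from 0.119% ± 0.0364 to 0.748% ± 0.359 (n = 6 each). Each rise with age separated all old from all young libraries (log2 difference 5.37 in WT, 4.29 in mKO and 2.55 in mTG, exact permutation tests, adjusted p = 0.00379 for each). At 24 months the share was lower than WT in mTG by 3.86 on the log2 scale (adjusted p = 0.00379) and in mKO by 1.15 (adjusted p = 0.0253, exact permutation tests). Other RNA classes went the same way with age in WT: small nuclear RNA from 0.00396% to 0.141%, small nucleolar RNA from 0.00485% to 0.0395%, microRNA loci from 0.0546% to 2.19% and mitochondrial rRNA from 0.277% to 3.64%, but histone transcripts went from 0.0273% to 0.0226%. Transcripts of the 13 protein genes of mitochondrial DNA took 26.6% ± 1.45 of TPM in young WT, 22.5% ± 4.83 in young mKO and 42.8% ± 2.56 in young mTG. The shares at 24 months were 22.4% ± 1.88, 20.3% ± 1.66 and 39.6% ± 5.50. The mTG share exceeded WT by 16.2 points at 3 months and 17.2 points at 24 months, with all libraries separated (exact permutation tests, adjusted p = 0.00758 for both). In WT the share differed by -4.22 points with age (adjusted p = 0.0101), but by 0.761 after scaling (adjusted p = 0.460, exact permutation tests). At 3 months mKO against WT gave -4.12 points (adjusted p = 0.102) and -5.41 without mKO_3mo replicate MKO_3251 (adjusted p = 0.0250), but -2.30 without MKO_3259 (adjusted p = 0.178, exact permutation tests). Adding 10 nuclear pseudogene copies, 95.9% to 100% identical to mitochondrial genes, raised every group's share and made that difference -7.73 points (adjusted p = 0.0152, exact permutation test).

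**Figure D2:**
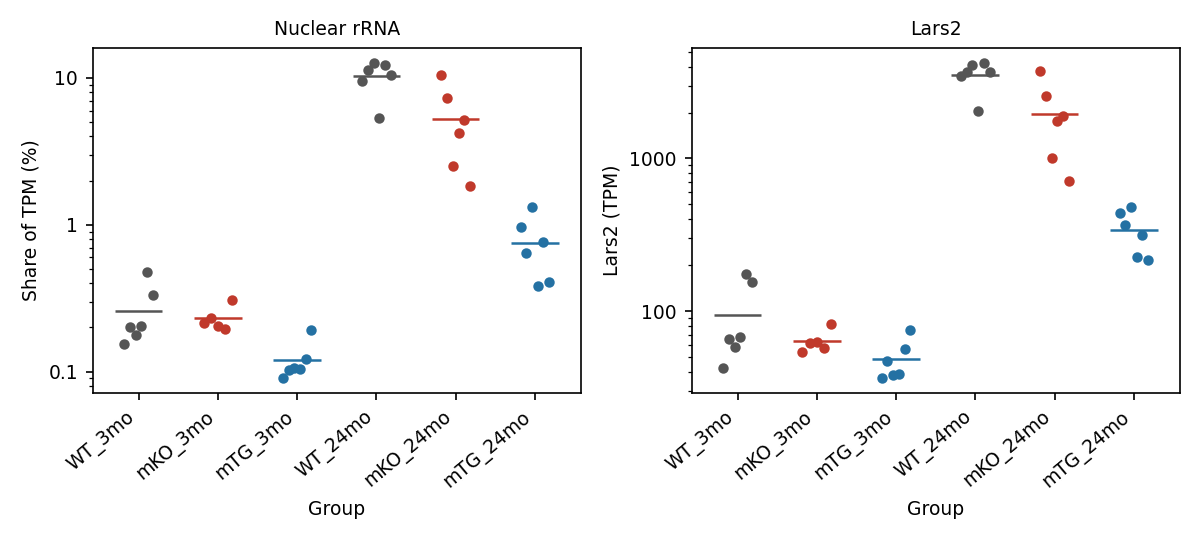
The share of TPM in nuclear ribosomal RNA genes in percent (left) and Lars2 in TPM (right) by group, both on log axes. Each panel has 1 point per library and a bar at each group mean. The rRNA share averaged 0.259% in young and 10.2% in old WT, and Lars2 averaged 94.0 and 3529 TPM there.

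Because TPM in a column add to a fixed total, these shares moved the median of all 12399 tested genes: by -0.23 (log2) with age in WT, -0.58 in mTG at 3 months, 0.28 in mKO at 24 months and -0.38 in mTG at 24 months, and by 0.24 and 0.21 in the interactions of age with mKO and mTG. Changes are therefore given relative to the median gene, after median-of-ratios scaling of the columns ("scaled TPM"), as log2 fold change ± SE from limma, with the result on unscaled TPM beside each count. "Rose" and "fell" refer to these scaled values at an adjusted p below 0.05. Across 10870 nuclear protein-coding genes, scaled changes followed transcript length with Spearman rho -0.249, 0.277 and -0.378 for age in WT, mKO and mTG, -0.269 and -0.098 for mKO and mTG at 3 months and 0.259 and -0.152 at 24 months.

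Ageing in wild-type muscle was addressed by WT at 24 against 3 months (n = 6 each). Collagen and matrix genes fell, among them Col1a1 (-1.57±0.13) and Col1a2 (-1.45±0.15), the chains of type I collagen, Sparc (-0.91±0.09), a collagen-binding matrix protein, and Col6a1 (-0.79±0.07). Of the extracellular matrix list, 1 rose and 16 fell of 25 (19 fell on unscaled TPM). For matrix genes camera gave adjusted p = 8.8e-14 and 0.188 with an estimated correlation. Also among the largest falls were Slc25a25 (-2.08±0.49), a mitochondrial ATP-Mg/phosphate carrier, Actc1 (-2.05±0.33), cardiac alpha-actin, Plin3 (-1.44±0.18), a lipid droplet coat protein, and Smox (-1.38±0.25), which oxidises spermine. The largest rises by the naming rule were short RNA genes: n-R5s100 (8.11±0.76), a 5S rRNA gene, Rn7s1 (7.28±0.47) of the signal recognition particle, Rpph1 (6.21±0.39) of ribonuclease P, Rn7sk (6.32±0.42), Mir6236 (6.22±0.36) and Vaultrc5 (5.79±0.36), a vault RNA. Among protein genes, chosen after the values were seen, Sln (2.62±0.31), an inhibitor of the sarcoplasmic calcium pump, Mss51 (2.48±0.31), a muscle metabolic regulator, Ccl8 (1.86±0.24), a chemokine, and Kcnab1 (1.78±0.09) were among the rises, as was Lars2 (5.67±0.33), the mitochondrial leucyl-tRNA synthetase, whose transcript shares 72 bases at 98.6% identity with the rRNA-like gene Gm15564 and is uncertain for that reason.

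By group, cytosolic ribosome genes rose with age in WT: 47 higher of 73 (9 higher on unscaled TPM, 58 higher over the list alone), with Rpl35 (1.12±0.16) and Rps7 (0.84±0.11). Camera gave cytosolic ribosome genes adjusted p = 3.17e-17 and 0.499 with an estimated correlation. Many of these genes have near-identical pseudogenes, so their single values are uncertain, and change fell with transcript length in this comparison (rho -0.249). Antigen presentation genes rose, 9 higher of 14 (4 higher on unscaled TPM, 12 higher over the list alone), with H2-Aa (0.86±0.14) and H2-DMa (0.58±0.12). The antigen presentation genes had a camera adjusted p = 1.06e-05 and 0.4 with an estimated correlation. Of macrophage and myeloid markers, 7 rose of 13 (5 rose on unscaled TPM, 8 rose over the list alone), with Tyrobp (0.65±0.13) and C1qc (0.66±0.13). For macrophage and myeloid markers camera gave adjusted p = 0.0002 and 0.4 with an estimated correlation. The denervation response list, genes induced when muscle loses its nerve, had 6 higher and 1 lower of 14 (5 higher and 3 lower on unscaled TPM) with age in WT, led by Krt18 (1.94±0.30) and Runx1 (0.64±0.10) up and Myh8 (-0.35±0.05) down. Camera gave denervation genes adjusted p = 0.0182 and 0.4 with an estimated correlation. Of glycolysis and glycogen genes, 11 fell of 22 (19 fell on unscaled TPM, 12 fell over the list alone), with Pkm (-0.49±0.07) and Pfkm (-0.29±0.07). The glycolysis genes had a camera adjusted p = 0.0002 and 0.4 with an estimated correlation. Endothelial markers had 7 lower of 14 (12 lower on unscaled TPM), with Tie1 (-0.41±0.05) and Eng (-0.62±0.13). For endothelial markers camera gave adjusted p = 0.000848 and 0.315 with an estimated correlation.

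Of the mitochondrial translation lists, the subject of the series, that of ribosome genes changed direction with the scaling in WT ageing, while most called members of the factors and tRNA enzymes were lower on both scales. Of mitochondrial ribosome genes, 13 rose and 3 fell of 80 (4 rose and 30 fell on unscaled TPM, 10 rose and 3 fell over the list alone, median 0.10, against -0.17 on unscaled TPM; camera adjusted p = 0.013 and 0.771 with an estimated correlation, and adjusted p = 0.927 on unscaled TPM), and Mrps2 (-0.36±0.07) was lower on both scales. The per-animal score, the mean log2 value of the list, was 0.15 higher on scaled TPM in all 6 old libraries and -0.14 on unscaled TPM (exact permutation tests, adjusted p = 0.00505 and 0.00568 over 42). Of mitochondrial translation factors and tRNA enzymes, 1 rose and 9 fell of 53 (1 rose and 34 fell on unscaled TPM), with Lrpprc (-0.43±0.08), a regulator of mitochondrial mRNA, and Mto1 (-0.21±0.07), a tRNA-modifying enzyme, lower (Mto1 turned to 0.002 with the rRNA share as covariate). The median of this list was -0.09 on scaled TPM. Its per-animal score differed by 0.00 (adjusted p = 0.952), and by -0.11 without Lars2 (adjusted p = 0.0152, exact permutation tests), a test added after the values were seen. Camera gave translation factors and tRNA enzymes adjusted p = 0.0402 and 0.678 with an estimated correlation. Nuclear-encoded respiratory chain genes had 21 higher and 1 lower of 77 (2 higher and 13 lower on unscaled TPM, 27 higher and 1 lower over the list alone, median 0.24, against -0.06 on unscaled TPM; camera adjusted p = 1.43e-05 and 0.767 with an estimated correlation), with Sdha (-0.31±0.07) the single fall on scaled TPM. In total 1409 genes were called higher by limma and 1403 lower of 12399 tested, against 461 higher and 5423 lower on unscaled TPM; 455 were higher and 1403 lower on both. With the log2 rRNA share as covariate, 5 genes were called on scaled TPM, all of them among those called before: that share separates the ages, the median SE went from 0.104 to 0.313, and the median absolute change of the genes called before went from 0.37 to 0.30.

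The libraries labelled mKO were compared at 24 (n = 6) and 3 months (n = 5) to follow ageing under that label. Denervation response genes had 7 higher of 14 (8 higher on unscaled TPM, 10 higher over the list alone), with Krt18 (2.53±0.31), Ankrd1 (1.70±0.28), Myh3 (1.05±0.14) and Runx1 (0.62±0.10). The denervation genes had a camera adjusted p = 2.58e-08 and 0.0141 with an estimated correlation (0.0652 on unscaled TPM). Of slow fibre genes, 3 rose of 12 (2 rose on unscaled TPM, 4 rose over the list alone), with Casq2 (0.56±0.13) and Myl2 (0.80±0.25). For slow fibre genes camera gave adjusted p = 0.00356 and 0.463 with an estimated correlation. The unscaled call for Myl2 ended without mKO_3mo replicate MKO_3265 (0.76, adjusted p = 0.0587). Matrix genes fell, 19 lower of 25 (18 lower on unscaled TPM, 20 lower over the list alone, camera adjusted p = 1.99e-22 and 0.0141 with an estimated correlation (0.0666 on unscaled TPM)), including Col1a1 (-1.54±0.14), Sparc (-0.92±0.10), Chad (-1.72±0.29) and Fmod (-1.68±0.26), and so did markers of fibro-adipogenic progenitors, 8 lower of 10 (6 lower on unscaled TPM, 9 lower over the list alone), with Cd248 (-0.62±0.08) and Gsn (-0.68±0.10). Camera gave fibro-adipogenic progenitor markers adjusted p = 1.71e-08 and 0.0218 with an estimated correlation (0.0652 on unscaled TPM). Of adipocyte markers, 4 fell of 9 (7 fell over the list alone), with Cfd (-1.88±0.40), adipsin, and Fabp4 (-0.48±0.12). The adipocyte markers had a camera adjusted p = 0.00153 and 0.331 with an estimated correlation. Cyp2e1 (-1.95±0.37) also fell. Short RNA genes again rose the most by the rule, n-R5s100 (9.08±0.80), Rn7s1 (6.74±0.49), Rpph1 (5.32±0.41), Vaultrc5 (5.20±0.38), n-R5s106 (4.67±0.41) and Mir6236 (4.91±0.38), as did Lars2 (4.69). Among protein genes chosen after the values were seen, Mss51 (2.67±0.33), Igfn1 (2.62±0.27) and Sln (2.17±0.32) rose.

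In the ageing of the libraries labelled mKO, mitochondrial ribosome genes had 4 lower of 80 (2 lower on unscaled TPM, 1 lower over the list alone, median -0.14; camera adjusted p = 2.69e-05 and 0.62 with an estimated correlation), and the per-animal score differed by -0.13 on scaled TPM (exact permutation test, adjusted p = 0.467). Nuclear-encoded respiratory chain genes had 2 lower of 77 (3 lower on unscaled TPM, 0 past the limma threshold over the list alone, with 0 higher and 20 lower at unadjusted p < 0.05). For respiratory chain genes the median was -0.20, with camera adjusted p = 4.29e-07 and 0.605 with an estimated correlation. Their score differed by -0.21 on scaled and -0.18 on unscaled TPM (exact permutation tests, adjusted p = 0.366 and 0.0909). On unscaled TPM it was -0.20 with mitochondrial genes removed (adjusted p = 0.0492) and -0.11 without MKO_3259 (adjusted p = 0.156). Of 12399 genes limma called 752 higher and 615 lower, against 624 higher and 433 lower on unscaled TPM. Counts higher and lower were 894 and 188 with nuclear protein-coding genes alone, 787 and 832 with quantile normalization, 501 and 537 with mitochondrial genes removed, 659 and 916 with array weights and 521 and 881 without MKO_3259 and mTG_24mo replicate MCK_SO_17. With the rRNA share as covariate 23 genes were called on scaled TPM (median SE 0.109 before and 0.260 after, median absolute change 0.40 and 0.40), and on unscaled TPM 370 with only these 11 libraries fitted.

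In mTG, 24 against 3 months (n = 6 each) asked how ageing proceeds with PGC-1α raised. Matrix genes fell here too, 18 lower of 25 (17 lower on unscaled TPM, 19 lower over the list alone, camera adjusted p = 3.69e-27 and 0.00612 with an estimated correlation (0.0523 on unscaled TPM)), with Col1a1 (-1.80±0.13), Col1a2 (-1.66±0.15), Col3a1 (-1.52±0.14), Sparc (-1.37±0.09) and Col4a1 (-1.19±0.13), a basement membrane collagen. Nrep (-1.30±0.14) also fell. Cytosolic ribosome genes had 33 higher of 73 (27 higher on unscaled TPM, 62 higher over the list alone), with Rpl23a (0.46±0.11) and Rpl5 (0.43±0.10), where change fell with transcript length (rho -0.378). Camera gave cytosolic ribosome genes adjusted p = 7.1e-19 and 0.574 with an estimated correlation. Erythrocyte markers rose as well, 4 higher of 5 (3 higher on unscaled TPM, 5 higher over the list alone), with Hbb-bt (0.81±0.18) and Alas2 (0.59±0.14). The erythrocyte markers had a camera adjusted p = 0.00138 and 0.554 with an estimated correlation. Of denervation response genes, 5 rose of 14 (3 rose on unscaled TPM, 7 rose over the list alone), with Ankrd1 (1.57±0.26) and Gadd45a (0.69±0.15). For denervation genes camera gave adjusted p = 0.00451 and 0.377 with an estimated correlation. Of fatty acid oxidation genes, 5 fell of 26 (4 fell on unscaled TPM, 6 fell over the list alone), with Slc25a20 (-0.42±0.08), the carnitine-acylcarnitine carrier, Cpt2 (-0.38±0.11) and Acsl1 (-0.56±0.15). Camera gave fatty acid oxidation genes adjusted p = 0.00165 and 0.674 with an estimated correlation. Their score differed by -0.21 on scaled and -0.23 on unscaled TPM (exact permutation tests, adjusted p = 0.0578 and 0.00568). On unscaled TPM the call for Gadd45a ended without mTG_24mo replicate MCK_SO_59 (0.54, adjusted p = 0.0627), and that for Acsl1 without mTG_24mo replicates MCK_SO_17 (-0.40, adjusted p = 0.124) and MCK_SO_25 (-0.57, adjusted p = 0.0560) and mTG_3mo replicates MCK_3875 (-0.56, adjusted p = 0.0641), MCK_3885 (-0.56, adjusted p = 0.0580) and MCK_3890 (-0.58, adjusted p = 0.0511). By the rule the largest rises were n-R5s100 (8.004±0.76), Rn7s1 (5.81±0.47), n-R5s106 (4.06±0.39), Rn7sk (3.46±0.42), Rmrp (3.55±0.59) and Mir6236 (3.30±0.36), and protein genes chosen afterwards were Ostn (2.78±0.14), the muscle-secreted peptide musclin, Sln (2.36±0.31), Ccl8 (2.07±0.24) and Mss51 (1.98±0.31). Lars2 changed by 2.80. The mitochondrial ribosome score differed by 0.07 on scaled TPM (exact permutation test, adjusted p = 0.627). In total 831 genes were called higher by limma and 925 lower of 12399 tested, against 390 higher and 351 lower on unscaled TPM. Without mTG_24mo replicate MCK_SO_17 the unscaled count was 379, and with the rRNA share as covariate 151 genes were called on scaled TPM (median SE 0.104 before and 0.175 after, median absolute change 0.37 and 0.34).

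Across the 12399 genes, which are not independent replicates, scaled age effects in WT correlated with those in mKO (Pearson r = 0.615, Spearman rho = 0.254) and mTG (r = 0.603, rho = 0.485). These comparisons share no library. WT and mKO shared 337 rises and 256 falls, where independent lists of these sizes would share 85.5 and 69.6; WT and mTG shared 371 and 397, against 94.4 and 105. Between mKO and mTG, r was 0.435 and rho 0.088.

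In young muscle, the libraries labelled mKO (n = 5) were compared with WT (n = 6) at 3 months. Some genes of oxidative metabolism were lower. Of the TCA cycle list, 12 fell of 18 (10 fell on unscaled TPM, 15 fell over the list alone), with Pdha1 (-0.59±0.09) and Dlat (-0.68±0.12) of the pyruvate dehydrogenase complex and Mdh2 (-0.47±0.11). The TCA cycle genes had a camera adjusted p = 8.4e-17 and 0.0541 with an estimated correlation. Of nuclear-encoded respiratory chain genes, 12 fell of 77 (10 fell on unscaled TPM, 15 fell over the list alone), with Cox7a1 (-0.84±0.20), a muscle subunit of cytochrome oxidase, Uqcrc2 (-0.39±0.07) of complex III and Sdha (-0.39±0.08) of complex II. For respiratory chain genes camera gave adjusted p = 1.38e-09 and 0.797 with an estimated correlation. Protein genes of mitochondrial DNA had 3 lower of 13 (0 past the limma threshold on unscaled TPM, with 0 higher and 8 lower at unadjusted p < 0.05, 8 lower over the list alone), with mt-Cytb (-0.52±0.16) and mt-Co1 (-0.49±0.14); their adjusted p was 0.0943 and 0.0946 on unscaled TPM, and below 0.05 there without mKO_3mo replicate MKO_3251 (0.0200 and 0.0251). Without MKO_3259 the unscaled values were -0.21 and -0.20 (adjusted p = 0.287 and 0.287). Camera gave genes of mitochondrial DNA adjusted p = 0.000334 and 0.354 with an estimated correlation. Of fatty acid oxidation genes, 5 fell of 26 (3 fell on unscaled TPM), with Acadl (-0.55±0.11) and Etfdh (-0.38±0.09) (camera adjusted p = 1.13e-06 and 0.529 with an estimated correlation), and of branched-chain amino acid catabolism, 5 fell of 16 (2 fell on unscaled TPM, 6 fell over the list alone), with Auh (-0.66±0.11). The amino acid catabolism genes had a camera adjusted p = 0.000334 and 0.354 with an estimated correlation. Per animal, the TCA cycle score differed from WT by -0.36 on scaled TPM (adjusted p = 0.0303). The scores of the respiratory chain (-0.21, adjusted p = 0.279), fatty acid oxidation (-0.26, adjusted p = 0.175) and mitochondrial DNA genes (-0.30, adjusted p = 0.105) did not pass (exact permutation tests). On unscaled TPM the respiratory chain score was -0.16 (adjusted p = 0.159), -0.24 without MKO_3259 (adjusted p = 0.0190) and -0.24 with mitochondrial genes removed (adjusted p = 0.0101). That of mitochondrial DNA genes was -0.25 (adjusted p = 0.213) and -0.07 without MKO_3259 (adjusted p = 0.519). By the naming rule the largest rises were Car3 (1.47±0.16), carbonic anhydrase 3, Dynlt1b (1.04±0.10), Ift122 (0.81±0.14), Rab4a (0.79±0.14) and Rhbdl1 (0.76±0.20); C1qtnf4 (0.77±0.24) was called on unscaled TPM and had adjusted p = 0.051 after scaling and 0.0647 (0.64) without mKO_3mo replicate MKO_3259. The largest falls by that rule were Kcng4 (-1.43±0.17), Aspa (-1.21±0.14), Efcab6 (-0.93±0.17), Nceh1 (-0.89±0.14), Lyrm7 (-0.86±0.20), an assembly factor of complex III, and Nsun4 (-0.79±0.14), a methyltransferase of mitochondrial rRNA. The call for Lyrm7 ended without mKO_3mo replicate MKO_3248 (-0.66, adjusted p = 0.0509 on unscaled TPM), that for Sdha without MKO_3259 (-0.25, adjusted p = 0.0517), and that for Etfdh without any of 7 libraries: WT_3mo replicates WT_2 (-0.33, adjusted p = 0.0609), WT_3 (-0.31, adjusted p = 0.0847), WT_4 (-0.28, adjusted p = 0.108) and WT_5 (-0.33, adjusted p = 0.0577) and mKO_3mo replicates MKO_3247 (-0.32, adjusted p = 0.0949), MKO_3259 (-0.24, adjusted p = 0.107) and MKO_3265 (-0.32, adjusted p = 0.0727).

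In young mKO 0 of 80 mitochondrial ribosome genes were called (1 higher and 11 lower at unadjusted p < 0.05; median -0.02, against 0.03 on unscaled TPM; camera adjusted p = 0.674). The scaled score was 5.354 in mKO_3mo replicate MKO_3259, 4.625 to 4.909 in the other mKO libraries and 4.795 to 4.944 in WT. Of 12399 genes limma called 222 higher and 406 lower, against 377 higher and 227 lower on unscaled TPM; 207 were higher and 216 lower on both. This comparison rested most on single libraries: the unscaled count of 604 ranged from 262 without MKO_3247 to 1288 without MKO_3251, was 391, 355 and 323 without WT_2, WT_3 and WT_4, and 399 without MKO_3248. With only these 11 libraries fitted, 8 genes were called, and 5 of 21 named genes kept their call.

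Raised PGC-1α in young muscle was addressed by mTG against WT at 3 months (n = 6 each). Mitochondrial genes rose relative to the median gene: of nuclear-encoded respiratory chain genes, 75 rose of 77 (41 rose and 4 fell on unscaled TPM, 76 rose over the list alone), with Atp5g3 (1.61±0.11) of ATP synthase and Sdhb (1.54±0.10) of complex II. For respiratory chain genes the median was 1.06, with camera adjusted p = 7.52e-33 and 0.164 with an estimated correlation. Of the TCA cycle, 17 rose of 18 (11 rose and 2 fell on unscaled TPM), with Dlat (1.80±0.12) and Mdh2 (1.52±0.10). Camera gave TCA cycle genes adjusted p = 2.95e-18 and 0.0468 with an estimated correlation. Of fatty acid oxidation genes, 24 rose of 26 (11 rose and 1 fell on unscaled TPM), with Acadvl (1.62±0.13) and Cpt2 (1.32±0.11). The fatty acid oxidation genes had a camera adjusted p = 7.11e-16 and 0.0949 with an estimated correlation (0.045 on unscaled TPM). Protein genes of mitochondrial DNA rose, 13 higher of 13 (10 higher on unscaled TPM), with mt-Atp6 (2.09±0.15) and mt-Co3 (1.46±0.11) (camera adjusted p = 4.11e-09 and 0.0468 with an estimated correlation); reads of both can fall on nuclear copies. Glycolysis and glycogen genes had 2 higher and 11 lower of 22 (21 lower on unscaled TPM), with Phkb (-1.91±0.09) and Ldha (-1.001±0.12), lactate dehydrogenase A, lower. For glycolysis genes camera gave adjusted p = 0.00165 and 0.409 with an estimated correlation. Of fast fibre genes, 1 rose and 9 fell of 13 (1 rose and 12 fell on unscaled TPM), with Myl1 (-1.08±0.12) and Casq1 (-0.73±0.11) lower. Camera gave fast fibre genes adjusted p = 0.00594 and 0.627 with an estimated correlation. The endothelial marker Pecam1 (0.56±0.08) rose, against -0.20 on unscaled TPM (adjusted p = 0.0896).

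The mitochondrial translation machinery rose relative to the median gene in young mTG and was lower on unscaled TPM. Of mitochondrial ribosome genes, 66 rose of 80 (12 rose and 36 fell on unscaled TPM, 67 rose over the list alone, median 0.60, against -0.17 on unscaled TPM; camera adjusted p = 9.11e-20 and 0.269 with an estimated correlation), and the per-animal score was 0.61 above WT on scaled TPM and -0.16 on unscaled TPM, with all 6 libraries separated in either direction (exact permutation tests, adjusted p = 0.00505 and 0.00568). Mrpl50, the member with the smallest p on unscaled TPM, gave 0.05 on scaled and -0.70 on unscaled TPM. Of mitochondrial translation factors and tRNA enzymes, 33 rose of 53 (7 rose and 33 fell on unscaled TPM, 35 rose over the list alone). The median of translation factors and tRNA enzymes was 0.37, against -0.32 on unscaled TPM (camera adjusted p = 4.11e-09 and 0.0468 with an estimated correlation (0.516 on unscaled TPM)). Beside Ppargc1a (3.67), the largest rises by the naming rule in young mTG were BC049352 (4.33±0.16), BC048679 (2.77±0.34), Adig (2.72±0.25), Cds1 (2.60±0.11), and Paqr4 (2.31±0.07); Sco2 (2.33±0.11), an assembly factor of cytochrome oxidase, was added after its value was seen. The largest falls by that rule were Smox (-3.72±0.25), Sec61g (-3.50±0.80) of the translocon, Mss51 (-3.38±0.31), Actc1 (-2.71±0.33), Prkag3 (-2.496±0.14) and Amd1 (-2.43±0.18), which with Smox acts in polyamine metabolism; Car3 (-2.30±0.15) fell where it rose in mKO. In total 2771 genes were called higher by limma and 2657 lower of 12399 tested, against 467 higher and 9573 lower on unscaled TPM; 1025 genes lower on unscaled TPM were higher after scaling.

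**Figure D3:**
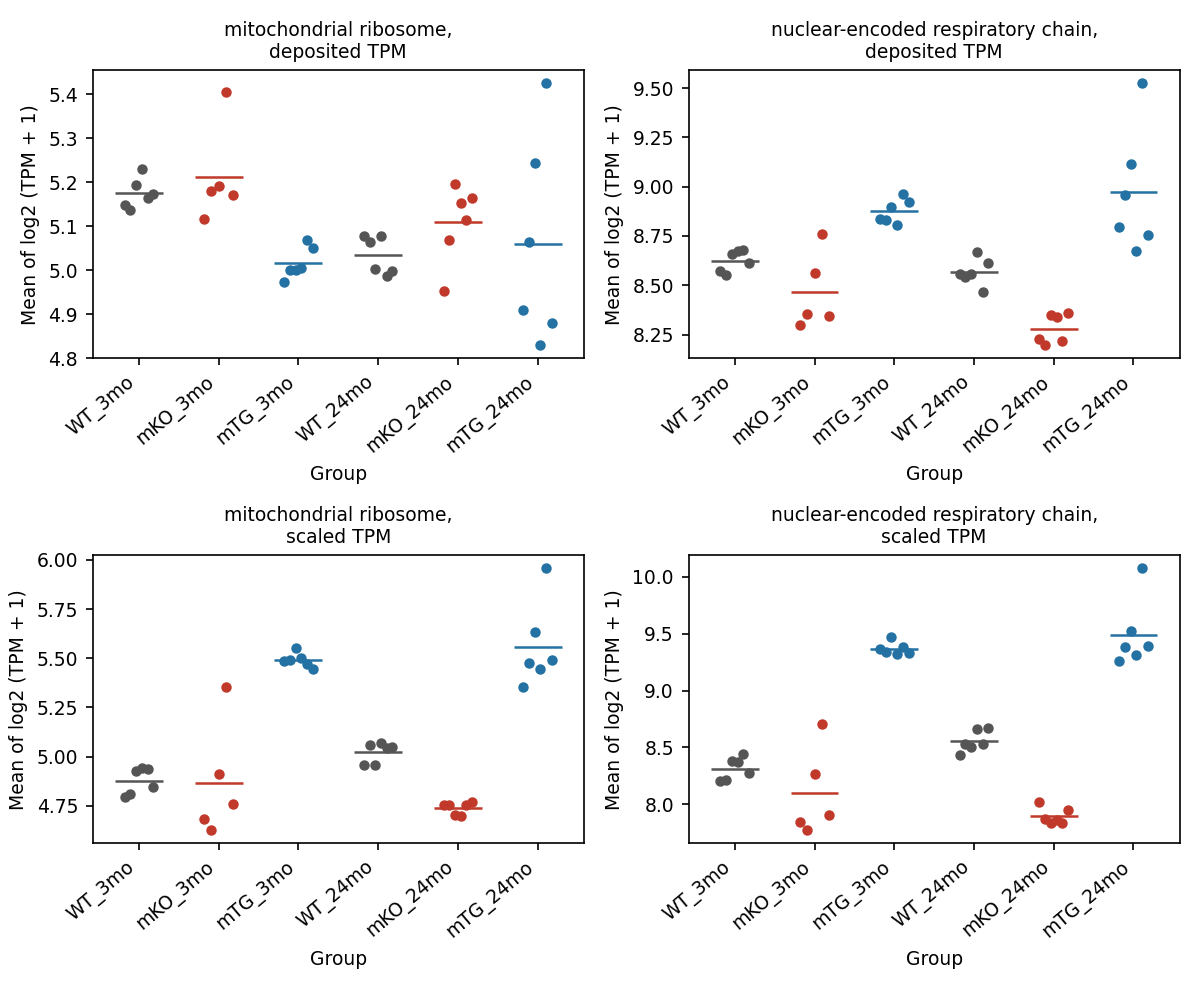
Mean log2(TPM + 1) over the members of the mitochondrial ribosome list (left) and the nuclear-encoded respiratory chain list (right). Unscaled TPM are above and scaled TPM below, with 1 point per library in 6 groups and a bar at each group mean. The mitochondrial ribosome score in mTG lay 0.61 above WT at 3 months and 0.54 at 24 months, where unscaled TPM gave -0.16 and 0.02, and the score in old mKO lay -0.28 from WT, against 0.07 on unscaled TPM.

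In old muscle, the libraries labelled mKO were compared with WT at 24 months (n = 6 each). Respiratory chain genes were lower on both scales: 72 lower of 77 (40 lower on unscaled TPM, 77 lower over the list alone), with Cox7a1 (-1.61±0.19), Atp5l (-1.13±0.16), Ndufb11 (-0.94±0.11) and Ndufc2 (-0.91±0.10). For respiratory chain genes the median was -0.65, with camera adjusted p = 7.16e-37 and 0.249 with an estimated correlation. The per-animal score of this list was -0.66 from WT on scaled and -0.29 on unscaled TPM, with all 6 libraries below all WT (exact permutation tests, adjusted p = 0.00505 and 0.00568). Protein genes of mitochondrial DNA had 6 lower of 13 (2 lower on unscaled TPM, 8 lower over the list alone), with mt-Nd6 (-0.92±0.12) and mt-Co3 (-0.63±0.11). Camera gave genes of mitochondrial DNA adjusted p = 0.000116 and 0.249 with an estimated correlation. Slow fibre genes rose, 10 higher of 12 (12 higher on unscaled TPM, 12 higher over the list alone), with Myh7 (1.88±0.30), Atp2a2 (1.28±0.25), Tnnt1 (0.97±0.23) and Casq2 (0.51±0.12). The slow fibre genes had a camera adjusted p = 1.63e-06 and 0.249 with an estimated correlation. Igfn1 (3.02±0.26), Car3 (2.04±0.15), Actc1 (1.96±0.33), Lrtm1 (1.77±0.17) and the long noncoding RNA AC138228.2 (1.87±0.26) were the other largest rises by the naming rule. The largest falls by it were the small nucleolar RNA genes Snora73a (-2.17±0.38) and Snora73b (-1.91±0.25), with Cyp2e1 (-1.52±0.35), Htra4 (-1.42±0.20) and Slc15a5 (-1.36±0.18); Ckmt2 (-1.24±0.14), the mitochondrial creatine kinase, and Cfd (-1.59±0.38) also fell. Antigen presentation genes were lower, 10 lower of 14 (1 lower on unscaled TPM, 13 lower over the list alone), with Psmb8 (-0.95±0.19) and H2-T23 (-0.54±0.11). For antigen presentation genes camera gave adjusted p = 6.48e-06 and 0.249 with an estimated correlation. On unscaled TPM H2-T23 had adjusted p = 0.0544, and was called without WT_24mo replicate WSO_29 (-0.27, adjusted p = 0.0399). Hbb-bt (-0.86±0.18) was lower, and its unscaled call ended without WT_24mo replicate WSO_15 (-0.32, adjusted p = 0.0620). Of cytosolic ribosome genes, 21 fell of 73 (6 rose and 1 fell on unscaled TPM, 22 fell over the list alone). Camera gave cytosolic ribosome genes, with a median of -0.30, against 0.07 on unscaled TPM, adjusted p = 2.24e-08 and 0.496 with an estimated correlation.

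Several mitochondrial groups in old mKO were lower than WT relative to the median gene, and level or higher on unscaled TPM. Of mitochondrial ribosome genes, 39 fell of 80 (19 rose and 2 fell on unscaled TPM, 49 fell over the list alone), with Mrpl12 (-0.84±0.12) (median -0.26, against 0.11 on unscaled TPM; camera adjusted p = 1.55e-11 and 0.342 with an estimated correlation), and the score was -0.28 from WT on scaled and 0.07 on unscaled TPM (exact permutation tests, adjusted p = 0.00505 and 0.164; 0.11 with adjusted p = 0.0182 on unscaled TPM without mKO_24mo replicate MKO_SO_23). Of the TCA cycle, 14 fell of 18 (2 rose and 1 fell on unscaled TPM, 15 fell over the list alone), with Pdhb (-0.65±0.08) and Pdha1 (-0.58±0.09). The median of TCA cycle genes was -0.37, against 0.00 on unscaled TPM (camera adjusted p = 1.14e-09 and 0.249 with an estimated correlation). Mitochondrial translation factors and tRNA enzymes split, 4 higher and 7 lower of 53 (31 higher and 2 lower on unscaled TPM), with Iars2 (0.12±0.04) among the rises. For translation factors and tRNA enzymes the median was -0.06, against 0.25 on unscaled TPM, with camera adjusted p = 0.326, and the opposite direction on unscaled TPM with adjusted p = 0.633. In total 1292 genes were called higher by limma and 1517 lower of 12399 tested, against 6359 higher and 343 lower on unscaled TPM; 1292 were higher and 340 lower on both. With the rRNA share as covariate 1894 were called on scaled TPM.

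Raised PGC-1α in old muscle was addressed by mTG against WT at 24 months (n = 6 each). The same mitochondrial groups rose: nuclear-encoded respiratory chain, 73 higher of 77 (52 higher and 2 lower on unscaled TPM), with Atp5b (1.76±0.14), Atp5g3 (1.59±0.11) and Sdhb (1.39±0.10) (camera adjusted p = 1.6e-26 and 0.259 with an estimated correlation); TCA cycle, 18 higher of 18 (16 higher on unscaled TPM), with Mdh2 (1.68±0.10) and Dlst (1.56±0.07). Camera gave TCA cycle genes adjusted p = 1.46e-18 and 0.0468 with an estimated correlation. Fatty acid oxidation had 24 higher of 26 (18 higher on unscaled TPM, 25 higher over the list alone), with Acadvl (1.71±0.13) and Cpt2 (1.502±0.11). The fatty acid oxidation genes had a camera adjusted p = 2.78e-14 and 0.0995 with an estimated correlation (0.0451 on unscaled TPM). Mitochondrial DNA genes had 12 higher of 13 (10 higher on unscaled TPM, 13 higher over the list alone), with mt-Atp6 (2.23±0.15) and mt-Co3 (1.31±0.11). For genes of mitochondrial DNA camera gave adjusted p = 4.18e-07 and 0.0786 with an estimated correlation (0.0233 on unscaled TPM). Of mitochondrial ribosome genes, 62 rose and 1 fell of 80 (27 rose and 22 fell on unscaled TPM, 64 rose and 1 fell over the list alone), with Dap3 (1.35±0.10), Mrpl37 (1.18±0.08) and Mrpl45 (1.17±0.09) (median 0.57; camera adjusted p = 2.43e-16 and 0.35 with an estimated correlation), and the score was 0.54 above WT on scaled TPM (exact permutation test, adjusted p = 0.00505) and 0.02 on unscaled TPM (adjusted p = 0.866). Of mitochondrial translation factors and tRNA enzymes, 37 rose and 1 fell of 53 (15 rose and 17 fell on unscaled TPM), with the elongation factor gene Tufm (1.40±0.10), Rmnd1 (1.38±0.10) and Qrsl1 (1.33±0.09) higher and Lars2 (-2.86±0.33) lower. Camera gave translation factors and tRNA enzymes, with a median of 0.43, against -0.05 on unscaled TPM, adjusted p = 1.58e-10 and 0.0468 with an estimated correlation (0.202 on unscaled TPM). Endothelial markers rose relative to the median gene, 12 higher of 14 (2 higher and 2 lower on unscaled TPM, 13 higher over the list alone), with Tie1 (0.71±0.05). The endothelial markers had a camera adjusted p = 3.98e-05 and 0.0682 with an estimated correlation.

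Beside Ppargc1a (4.12), the largest rises by the naming rule in old mTG were BC049352 (4.83±0.16), Kcng4 (3.03±0.16), which fell in young mKO, Adig (2.497±0.25), Ppif (2.35±0.09), cyclophilin D of the mitochondrial permeability pore, and Mybph (2.30±0.28). The largest falls by that rule were Mss51 (-3.89±0.31), Ighm (-3.04±0.40) and the short RNA genes Rn7sk (-3.58±0.42), CT010467.1 (-3.42±0.33), an annotated rRNA gene, Rpph1 (-3.01±0.39) and Mir6236 (-2.88±0.36), with Kcnab1 (-2.81±0.09) added after its value was seen. The falls of Rn7sk, CT010467.1, Rpph1, Mir6236 and Lars2 turned into positive values, 0.65, 0.30, 1.103, 0.85 and 0.69, with the rRNA share as covariate. Cytosolic ribosome genes had 1 higher and 16 lower of 73 (70 lower on unscaled TPM, 1 higher and 14 lower over the list alone). For cytosolic ribosome genes the median was -0.19, with camera adjusted p = 0.0164 and 0.853 with an estimated correlation. In total 2979 genes were called higher by limma and 2962 lower of 12399 tested, against 849 higher and 7714 lower on unscaled TPM; 299 genes lower on unscaled TPM were higher after scaling. With the rRNA share as covariate 1722 were called on scaled TPM, with the median SE going from 0.104 to 0.237.

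**Figure D4:**
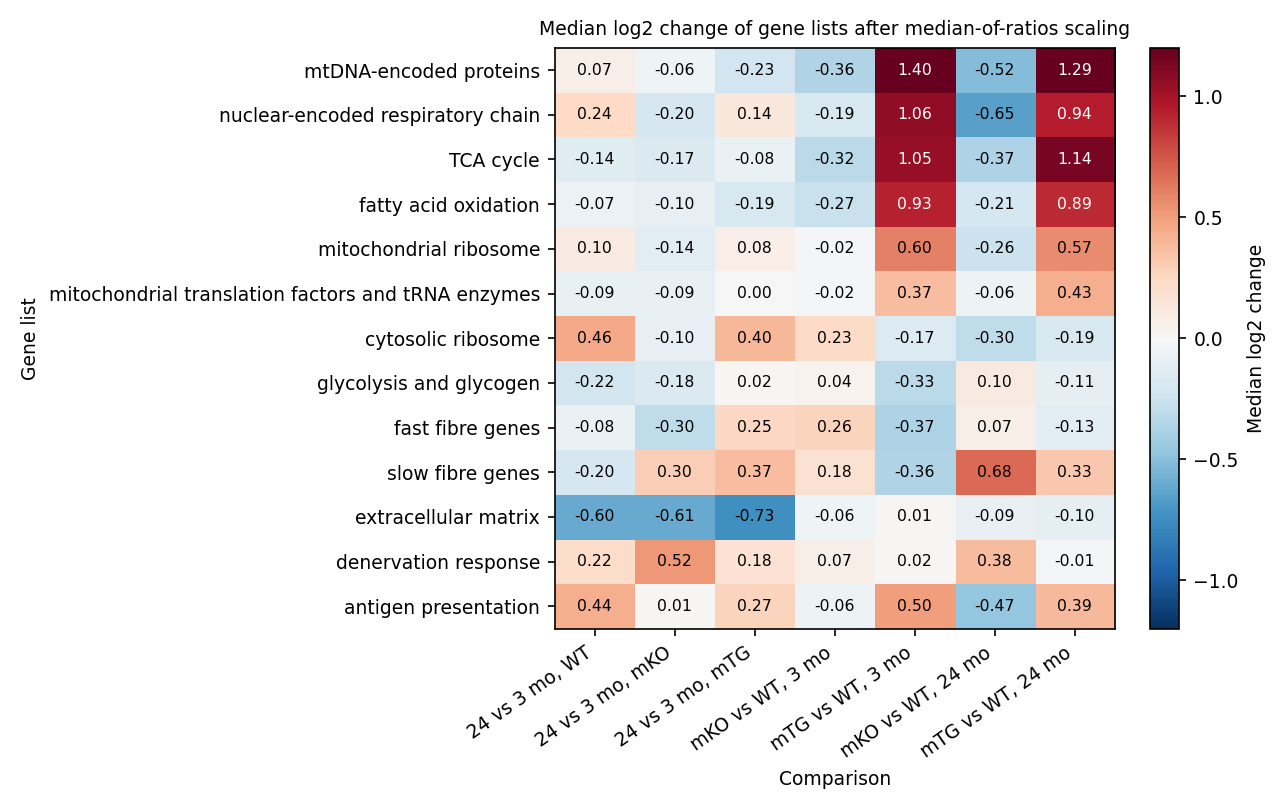
Median log2 fold change of gene lists (rows) in the 7 comparisons of 2 groups (columns) on scaled TPM. For mitochondrial ribosome genes the median in young mTG was 0.60, and for respiratory chain genes in old mKO it was -0.65. On unscaled TPM, which is not drawn, these medians were -0.17 and -0.27.

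Whether ageing differed between genotypes was tested as the age effect in mKO or mTG minus that in WT. For mKO, Ubr4 (0.97±0.14), Ddah1 (0.84±0.12), Gcnt2 (0.76±0.12) and Myh4 (0.55±0.11) had higher age effects than in WT. Lower ones were those of Dynlt1b (-1.28±0.14), Snora81 (-3.24±0.53), Rnu12 (-1.57±0.28), the U12 small nuclear RNA, Pld5 (-0.93±0.14) and Sult1e1 (-0.72±0.13). Ppargc1a itself gave 0.90 ± 0.28 with adjusted p = 0.0559 after scaling and 0.00833 before. For mTG, Ostn (2.00±0.20), BC051142 (1.60±0.17), Myh4 (0.85±0.11), Mfsd4b3 (0.77±0.12) and Mgme1 (0.61±0.08) had higher age effects. Lower ones were those of Kcnab1 (-1.63±0.13), Rnu12 (-1.95±0.28), Snord17 (-2.95±0.49), Rny1 (-2.60±0.47), a Y RNA, and AA474408 (-0.82±0.13). In the mKO interaction cytosolic ribosome genes had 11 lower of 73 (2 lower on unscaled TPM, 56 lower over the list alone). Camera gave cytosolic ribosome genes, with a median of -0.54, adjusted p = 4.33e-22 and 0.438 with an estimated correlation. Respiratory chain genes had 9 lower of 77 (2 higher and 2 lower on unscaled TPM, 42 lower over the list alone) there (median -0.44; camera adjusted p = 1.68e-17 and 0.485 with an estimated correlation), and mitochondrial ribosome genes 1 lower of 80 (3 higher on unscaled TPM, 12 lower over the list alone). The median of mitochondrial ribosome genes was -0.26, against 0.05 on unscaled TPM (camera adjusted p = 1.69e-09 and 0.54 with an estimated correlation). In the mTG interaction glycolysis and glycogen genes had 3 higher of 22 (17 higher on unscaled TPM, 7 higher over the list alone, camera adjusted p = 2.11e-05 and 0.956 with an estimated correlation), and slow fibre genes 2 higher of 12 (7 higher on unscaled TPM, 3 higher over the list alone). For slow fibre genes camera gave adjusted p = 0.00197 and 0.956 with an estimated correlation. The score of mitochondrial translation factors and tRNA enzymes gave 0.27 for mKO and 0.26 for mTG on unscaled TPM (permutation tests, adjusted p = 0.0158 and 0.0305 over 12) but -0.01 and 0.02 on scaled TPM (adjusted p = 0.979 for both). In the mKO interaction 307 genes were called higher by limma and 234 lower of 12399 tested, against 2996 higher and 108 lower on unscaled TPM, and 180 with the rRNA share as covariate on scaled TPM. In the mTG interaction 219 genes were called higher by limma and 213 lower of 12399 tested, against 2136 higher and 132 lower on unscaled TPM, and 23 with that covariate.

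Across genes, which are not independent replicates, scaled genotype effects at 3 and 24 months correlated with r = 0.752 (rho = 0.752) for mTG and r = 0.225 (rho = 0.187) for mKO. The mTG calls shared 2132 rises and 1871 falls between ages, where independent lists would share 666 and 635; the mKO calls shared 110 and 218, against 23.1 and 49.7. Effects of mKO and mTG at 3 months, taken against the same WT libraries, correlated with r = -0.295 (rho = -0.295), where 100 simulated pairs of unchanged groups gave 0.477 and giving each comparison its own WT libraries gave -0.342; the covariance was -0.0357 against 0.0137 simulated. There 321 genes fell in mKO and rose in mTG and 143 did the reverse, against 90.7 and 47.6 for independent lists, while 11 rose and 29 fell in both, against 49.6 and 87.0. At 24 months r was 0.075 (rho = -0.076), against 0.493 simulated and 0.002 with split controls, with a covariance of 0.0134 against 0.0135 simulated.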

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

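Among the tests in this part, those of more ribosomes per cell and of the 2 accounts of Lars2 were chosen after the results were seen, as were the rRNA share, the principal components and the length and rRNA corrections. Across 9 measures and 6 groups, 5 of 54 sets of values held a library far from its group by Dixon's test, where chance picks about 1 in 20. Ppargc1a in mTG_24mo replicate MCK_SO_17 was 43.68 TPM with the nearest library at 64.39 (gap over range 0.821). The rRNA share of mTG_3mo replicate MCK_3890 was 0.1909% against 0.1214% (0.696), and the mitochondrial ribosome score of mKO_3mo replicate MKO_3259 was 5.404 against 5.191 (0.741). In mKO_24mo replicate MKO_SO_23 the score of mtDNA-encoded proteins was 12.94 against 13.22 (0.639) and that of fatty acid oxidation 5.936 against 6.183 (0.656). The critical value is 0.625 for 6 libraries and 0.71 for 5.

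The age effect differed between genotypes by interaction tests, on unscaled TPM, for 3104 genes between mKO and WT and 2268 between mTG and WT. For mKO these included Ddah1 1.097, Ubr4 1.283, Gcnt2 1.026, Myh4 0.874, Dynlt1b -0.975, Snora81 -3.254, Rnu12 -1.552, Pld5 -0.764, Sult1e1 -0.623 and Ppargc1a 1.186 (log2). For mTG they included Ostn 2.185, Myh4 1.125, BC051142 1.338, Mgme1 0.828, Mfsd4b3 0.919, Kcnab1 -1.466, Rnu12 -1.933, Snord17 -3.185, Rny1 -2.957 and AA474408 -0.860. After scaling, Ppargc1a had adjusted p = 0.0559, and the other 19 values stayed past the limma threshold, with the highest adjusted p at 0.00614 (Myh4, mKO). Of the scores, mitochondrial translation factors and tRNA enzymes differed by 0.272 for mKO and 0.255 for mTG, the TCA cycle by 0.325 and fatty acid oxidation by 0.403 for mKO (permutation tests, adjusted p = 0.0158, 0.0305, 0.0371 and 0.0371). On scaled TPM none of the 4 passed these tests (TCA cycle 0.00490, fatty acid oxidation 0.0864, adjusted p = 0.979 for each).

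The rRNA share was higher at 24 than at 3 months in all 3 genotypes. If more RNA without a poly(A) tail had been carried into old libraries, histone transcripts lacking it would rise too. The histone sum was 220.7 ± 21.7 scaled TPM in WT_3mo and 224.5 ± 36.1 in WT_24mo (log2 difference 0.015). Of these, 5 of 70 genes made 87.3% of the sum, and the other 65 gave -0.367. Their tails and own age effects were not tested, so carry-over stays open. More ribosomes per cell would leave non-ribosomal RNA as it was, but 18 of 35 small nuclear, 7SK, 7SL, RNase P and RNase MRP genes rose in WT, with a median of 1.410. This argues against more ribosomes as the whole cause. A difference in library preparation between ages or age itself may be the source, not tested apart since every 24-month library belongs to 1 side. Either, if equal in all genotypes, would keep the 3-month log2 gap to WT (mTG -1.04, mKO -0.07). At 24 months it was -3.86 and -1.15, so the 24-month genotype comparisons and interactions carry this difference too.

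Lars2 rose with age in all 3 genotypes. Within groups, log2 Lars2 followed the log2 rRNA share over 35 libraries (r = 0.954, rho = 0.955, permutation p = 1e-05 for each, the smallest these permutations can give, and r = 0.936 without the 2 farthest libraries), as did Gm15564 (r = 0.918), which shares sequence with Lars2. A general rise of mitochondrial aminoacyl-tRNA synthetases would raise the others, but 0 of 15 rose in WT by limma (0 at unadjusted p < 0.05) and 2 were lower (5 at unadjusted p < 0.05; range -0.365 to 0.097). A candidate explanation is that rRNA reads were assigned to Lars2; a rise of Lars2 mRNA beneath them stays open and was not tested.

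Respiratory chain and cytosolic ribosome genes were lower in mKO than WT at 24 months on scaled TPM. There change followed transcript length across genes (Spearman rho 0.259). A trend on length or GC content would give matched random lists the same median. The respiratory chain median was -0.648. Of 10000 random lists, 95% lay from -0.243 to -0.095 matched on length and -0.125 to 0.029 on GC content (0.00% as low in either). The cytosolic ribosome median was -0.305 against -0.299 to -0.120 (1.35% as low) and -0.126 to 0.039 (0.00%). Random lists lack the correlation between members, so these ranges can be too narrow. The respiratory chain median lay far below both, which argues against these trends as its whole cause. For the ribosomal list length stays open. A lower PGC-1α activity stays open as a hypothesis that rests on the label, and fibre type, which also moved, was not tested apart from it.

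Whether chance can be excluded was asked with 100 splits of the libraries compared. In every comparison of 2 groups 1 of 100 splits, the real one, called as many genes, on unscaled and on scaled TPM. The real count and the highest other, with scaled TPM in brackets, were 6739 and 3 (3519 and 6) for age in WT, 370 and 44 (725 and 18) for age in mKO, 721 and 1 (977 and 2) for age in mTG, 8 and 1 (21 and 5) for mKO and 10377 and 7163 (6159 and 4) for mTG at 3 months, 7135 and 4720 (3688 and 2) for mKO and 8411 and 2338 (5206 and 2) for mTG at 24 months, and 3000 and 3 (434 and 5) for the mTG interaction, where again 1 of 100 splits reached the real count. For the mKO interaction they were 2453 and 4805 (522 and 335), with 2 of 100 splits reaching the real count on unscaled TPM. A split can share most libraries with the real one, so high counts before scaling cannot show another structure of the samples.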

How the results depend on the processing

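The tests with nuclear protein-coding genes, rRNA as a covariate, libraries left out together, the length trend, pseudogene copies and the list without Lars2 were chosen after results were seen. Called genes on unscaled TPM numbered 5884 for age in WT, 1057 for age in mKO, 741 for age in mTG, 604 for mKO at 3 months, 10040 for mTG at 3 months, 6702 for mKO at 24 months, 8563 for mTG at 24 months, 3104 for the mKO interaction, 2268 for the mTG interaction. A filter at a mean of 5 TPM, which tests fewer genes, gave 3622 for age in WT, 461 for age in mKO, 5453 for mTG at 3 months, 4073 for mKO at 24 months and 4831 for mTG at 24 months. Without a filter there were 1745 for age in mKO. A fold minimum of 1.5, which removes small changes by construction, gave 1139 for age in WT, 410 for age in mKO, 229 for age in mTG, 160 for mKO at 3 months, 6312 for mTG at 3 months, 1471 for mKO at 24 months, 3848 for mTG at 24 months, 1165 for the mKO interaction and 694 for the mTG interaction. Median-of-ratios scaling, which removes the shift of the median gene, gave 2812 for age in WT, 1756 for age in mTG, 5428 for mTG at 3 months, 2809 for mKO at 24 months, 541 for the mKO interaction and 432 for the mTG interaction. Quantile normalization gave 3176 for age in WT, 1619 for age in mKO, 1766 for age in mTG, 5601 for mTG at 3 months, 3142 for mKO at 24 months, 847 for the mKO interaction and 601 for the mTG interaction. Nuclear protein-coding genes alone, which also changes the base of the TPM total, gave 1886 for age in WT, 1325 for age in mTG, 4668 for mTG at 3 months, 2083 for mKO at 24 months, 5520 for mTG at 24 months, 360 for the mKO interaction and 293 for the mTG interaction. With only the groups compared, and so fewer samples, counts were 370 for age in mKO and 8 for mKO at 3 months. Array weights gave 2281 for mKO at 3 months and 4118 for the mTG interaction; the cause was not tested. The log2 rRNA share as covariate gave 1 for age in WT, 3 for age in mKO, 36 for age in mTG, 3338 for mTG at 24 months, 2057 for the mKO interaction and 154 for the mTG interaction. With scaling, the covariate gave 5 for age in WT, 23 for age in mKO, 151 for age in mTG, 4780 for mTG at 3 months, 1894 for mKO at 24 months, 1722 for mTG at 24 months, 180 for the mKO interaction and 23 for the mTG interaction. The covariate separates the ages and widens the SE (median 0.104 to 0.313 for age in WT). Scaling without MKO_3259 and MCK_SO_17 gave 3912 for age in WT, 1683 for age in mTG, 6188 for mTG at 3 months, 3839 for mKO at 24 months, 772 for the mKO interaction and 830 for the mTG interaction. Scaling with the length trend removed gave 3062 for age in WT, 1592 for age in mKO, 1772 for age in mTG, 5762 for mTG at 3 months, 3159 for mKO at 24 months, 583 for the mKO interaction and 588 for the mTG interaction. A pseudocount of 0.1, removal of mitochondrial genes, and leaving out both libraries without scaling kept all 9 counts within 1.5-fold. The removal left in nuclear copies (14.3% of TPM in young WT, 21.3% in young mTG).

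Leaving out the library in brackets gave counts of 262 (mKO_3mo replicate MKO_3247) to 1288 (MKO_3251) for mKO at 3 months. It gave 379 (mTG_24mo replicate MCK_SO_17) to 992 (MCK_SO_31) for age in mTG. For the mKO interaction it gave 2005 (MKO_3259) to 4181 (MKO_3248). The other counts stayed within 1.5-fold, from 5258 to 5947 for age in WT, 818 to 1351 for age in mKO, 9780 to 9962 and 8153 to 8503 for mTG at 3 and 24 months, 5860 to 6968 for mKO at 24 months and 1618 to 2691 for the mTG interaction.

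Scores turned or crossed the threshold with the scaling. The mitochondrial ribosome score, scaled against unscaled, was 0.146 against -0.141 for age in WT and 0.614 against -0.158 for mTG at 3 months. At 24 months it was -0.284 against 0.075 for mKO and 0.537 against 0.025 for mTG. With the length trend also removed these scaled values were, in order, 0.121, 0.596, -0.257 and 0.498. With mitochondrial genes removed from unscaled TPM it was 0.197 and 0.331 for mTG at 3 and 24 months. The score of translation factors and tRNA enzymes was 0.002 against -0.258 for age in WT and 0.449 against -0.249 for mTG at 3 months. At 24 months it was -0.082 against 0.242 for mKO and 0.467 against 0.006 for mTG. The interactions gave -0.007 against 0.272 for mKO and 0.018 against 0.255 for mTG. With the length trend also removed these scaled values were, in order, 0.033, 0.443, -0.096, 0.435, -0.018 and -0.007. With mitochondrial genes removed it was 0.067 and 0.286 for mTG at 3 and 24 months. Without Lars2 on scaled TPM it was -0.107 for age in WT (exact permutation test, adjusted p = 0.0152) and -0.096 for age in mKO. Also without Lars2 it was 0.458 and 0.531 for mTG at 3 and 24 months and -0.056 for mKO at 24 months. Scaling also turned the score of mtDNA-encoded proteins (0.086 against -0.214 for age in WT). The respiratory chain score turned (0.241 against -0.057 for age in WT, 0.161 with the length trend removed). So did that of the TCA cycle (-0.354 against 0.017 for mKO at 24 months, -0.362 with the length trend removed). The share of mitochondrial transcripts became 0.761 points for age in WT and -6.706 for mKO at 24 months with scaling, and -7.729 for mKO at 3 months with pseudogene copies. Leaving out 1 library gave -4.017 (without mKO_3mo replicate MKO_3259) to -0.903 (without MKO_3251) points for age in mKO, -5.414 (without MKO_3251) to -2.300 (without MKO_3259) for mKO at 3 months, and a mitochondrial ribosome score of 0.057 (without mKO_24mo replicate MKO_SO_85) to 0.106 (without MKO_SO_23) for mKO at 24 months. The camera test of the mitochondrial proteostasis list in the mKO interaction turned down on scaled TPM (adjusted p = 0.0148, against 0.927).

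Of named genes, Mrpl50 and Pecam1 in mTG at 3 months turned with scaling (0.052 and 0.562), quantile normalization (0.009 and 0.503) and scaling with the rRNA covariate (0.043 and 0.562). That covariate also turned Mto1 in age in WT (0.002), Rmrp in age in mTG (-0.127), and Rn7sk (0.649), CT010467.1 (0.303), Rpph1 (1.103), Mir6236 (0.851) and Lars2 (0.694) in mTG at 24 months. It kept 2 of 39 named genes called in age in WT and 3 of 31 in age in mKO. Quantile normalization ended the calls of mt-Co3 in mTG at 3 months (0.053, adjusted p = 0.671), mKO at 24 months (-0.008, adjusted p = 0.964) and mTG at 24 months (0.191, adjusted p = 0.0791). With only the groups compared, calls ended for Casq2 (adjusted p = 0.0510), Ciart (0.0865), Per1 (0.109) and Musk (0.192) in age in mKO, Rpl23a (adjusted p = 0.0518), Rpl5 (0.0665), Dbp (0.0552) and Acsl1 (0.0770) in age in mTG, Hbb-bt (adjusted p = 0.0571) in mKO at 24 months and 16 of 21 named genes in mKO at 3 months. Over 4465 pairs of a named gene and a setting, 4276 kept direction and side of the threshold, 159 lost and 17 gained a call and 13 turned. Leaving out 1 library made 39 of the losses and 3 of the gains. Of 360 list tests 145 were called, and 137 of these lost their call with the estimated correlation. No paired analysis was possible because the columns carry no shared replicate numbers, so the planned replicate block was not run, nor were the planned tests on counts, since the values are TPM. Depth is unknown, and what it limits could not be measured.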

Other observations

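Further lists were examined beyond those of the report, and they were picked after their values were seen. Regulators of mitochondrial biogenesis in mTG had 9 higher and 2 lower of 21 (4 higher and 14 lower on unscaled TPM) at 3 months (camera adjusted p = 0.00251 and 0.0534 with an estimated correlation), with the nuclear receptor gene Esrrb (1.77±0.10). At 24 months they had 10 higher and 2 lower of 21 (6 higher and 10 lower on unscaled TPM, 11 higher and 2 lower over the list alone, camera adjusted p = 0.00562 and 0.0786 with an estimated correlation), with Esrrb (1.54±0.10), Perm1 (1.30±0.10) and Sirt3 (1.38±0.12). In the libraries labelled mKO at 24 months Esrra (-0.91±0.12) was lower. Angiogenic factors in mTG had 6 higher and 1 lower of 11 (3 higher and 5 lower on unscaled TPM, 6 higher and 2 lower over the list alone) at 3 months (camera adjusted p = 0.0699, and adjusted p = 0.00137 on unscaled TPM), with Vegfb (1.78±0.11). At 24 months they had 6 higher and 1 lower of 11 (2 higher and 4 lower on unscaled TPM, 6 higher and 2 lower over the list alone, camera adjusted p = 0.0827, and adjusted p = 0.00541 on unscaled TPM), with Vegfb (1.94±0.11). Antioxidant genes in mTG had 7 higher and 2 lower of 17 (3 higher and 11 lower on unscaled TPM, 8 higher and 2 lower over the list alone) at 3 months (camera adjusted p = 0.0413 and 0.409 with an estimated correlation, and adjusted p = 0.12 on unscaled TPM), with Sod2 (1.66±0.10), the mitochondrial superoxide dismutase. At 24 months they had 9 higher and 2 lower of 17 (4 higher and 6 lower on unscaled TPM, 10 higher and 2 lower over the list alone, camera adjusted p = 0.0295 and 0.379 with an estimated correlation), with Sod2 (1.52±0.10) and Prdx6 (1.21±0.07). Among atrophy genes, myostatin Mstn (-1.97±0.09) and the ubiquitin ligases Trim63 (-0.96±0.11) and Fbxo32 (-0.70±0.10) were lower in mTG at 3 months, and Mstn (-1.72±0.09), Trim63 (-0.71±0.11) and Fbxo32 (-0.60±0.10) at 24 months. The list had 2 higher and 3 lower of 15 (1 higher and 12 lower on unscaled TPM) at 3 months and 2 higher and 3 lower of 15 (2 higher and 11 lower on unscaled TPM) at 24 months.

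Some circadian clock genes rose with age: 2 higher and 1 lower of 16 (2 higher and 2 lower on unscaled TPM) in WT, 5 higher of 16 (5 higher and 1 lower on unscaled TPM, 6 higher and 1 lower over the list alone) in mKO and 4 higher of 16 (3 higher on unscaled TPM, 5 higher over the list alone) in mTG. Members were Cry2 (0.60±0.08) in WT, Cry2 (0.78±0.09) and Per1 (0.98±0.29) in mKO, and Cry2 (0.60±0.08) and Dbp (1.13±0.26) in mTG. Times of tissue collection were not used here. Cry2 (0.49±0.08) and Per1 (1.08±0.27) were also higher in mKO than WT at 24 months. With age Ciart (0.84±0.23) rose in WT, Ciart (0.97±0.24) in mKO and Ciart (0.90±0.23) in mTG. On unscaled TPM the call for Ciart in WT ended without WT_3mo replicate WT_5 (0.55, adjusted p = 0.0584), WT_6 (0.55, adjusted p = 0.0624) or WT_24mo replicate WSO_29 (0.58, adjusted p = 0.0555). In mTG it ended without any of mTG_3mo replicate MCK_3875 (0.80, adjusted p = 0.0594), MCK_3876 (0.82, adjusted p = 0.0510), MCK_3885 (0.71, adjusted p = 0.0866), MCK_3887 (0.79, adjusted p = 0.0595), MCK_3890 (0.80, adjusted p = 0.0529), mTG_24mo replicate MCK_SO_59 (0.72, adjusted p = 0.0860) or MCK_SO_61 (0.64, adjusted p = 0.0839). For Per1 in mKO it ended without mKO_3mo replicate MKO_3251 (0.98, adjusted p = 0.0600), MKO_3259 (0.79, adjusted p = 0.0983), MKO_3265 (0.95, adjusted p = 0.0675), mKO_24mo replicate MKO_SO_32 (0.97, adjusted p = 0.0569) or MKO_SO_87 (0.96, adjusted p = 0.0609).

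Genes of the neuromuscular junction had 3 higher of 15 with age in mKO, namely the acetylcholine receptor genes Chrna1 (1.07±0.15) and Chrnb1 (0.88±0.09) and the kinase gene Musk (0.56±0.17) (camera adjusted p = 0.0351 and 0.331 with an estimated correlation). On unscaled TPM the call for Musk ended without mKO_3mo replicate MKO_3247 (0.57, adjusted p = 0.0734), MKO_3251 (0.62, adjusted p = 0.0514), MKO_3259 (0.38, adjusted p = 0.153), mKO_24mo replicate MKO_SO_87 (0.58, adjusted p = 0.0664), MKO_SO_68 (0.54, adjusted p = 0.0863) or MKO_SO_70 (0.58, adjusted p = 0.0634), and with a pseudocount of 0.1 (adjusted p = 0.0666).

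Principal components of scaled log2 values held 37.7%, 16.2% and 8.7% of the variance. The mean on component 1 was 42.88 in mTG_3mo and 32.94 in mTG_24mo, and from -31.60 to -6.60 in the other groups. On component 3, mKO_3mo replicate MKO_3259 had 57.37 and mTG_24mo replicate MCK_SO_17 42.02, and the next highest absolute value was 12.82.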
